A study of Homo sapiens with 23 samples.

How the data were processed

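Single-cell (inDrop) and spatial (ST) counts of pancreatic ductal adenocarcinoma were used: 13 inDrop libraries of tumours A, B and C and 10 ST sections of tumours A, B, D, E, F and G. Each letter of the labels was taken as 1 tumour of 1 donor, although the series text counts 6 patients and the letters are 7. The deposited tables hold raw counts per gene and barcode or spot, as whole numbers without normalization, and per the submitters' processing notes STAR 2.5.1 and HTSeq were used with hg38, with Bowtie2 also named for some samples. The notes do not give the order of these steps or any filter. The authors also deposited counts of annotated cells of A and B, whose columns are named by population and not by library. Lists of barcodes and spot positions without measurements were not used. For the first sections of A and B the deposited tables of filtered spots were used in place of those of all array spots. ST and annotated tables hold 0 mitochondrial and 23 ribosomal protein genes (0 of each in the table of F), against 13 and 97 in the inDrop tables, so the ST and inDrop tables were compared over shared genes only. Genes are given by symbol as in the tables, without coordinates.

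The ST table of F ends partway through a gene and holds 5757 complete genes, so F was left out of the spot splits, which were planned with 6 tumours and run with 5 (A, B, D, E and G). A fit with F on the genes of its table was added after the data were seen, as were a ranking of the cells within each cluster of a library and list levels without each section of A and B. F entered a pair of lists where its table held at least 3 genes of each. In the section of D, 31 repeated columns of 29 spots, identical in each of the 29, were removed. Rows with gene symbols turned into dates (27 in an ST table, 1 in that of F) and sex-linked genes named in the rule below were left out before any comparison.

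ST spots with at least 500 counts were used (610 of A, 552 of B, 418 of D, 350 of E, 268 of F and 246 of G). A list's score in a spot or cell was the mean over its genes of the z-scored log of counts per 10000 with a pseudocount of 1, made residual on the log of the total count. The 31 lists (19 of cell types, 12 of processes) were fixed before the data were examined, as were the comparisons, tests, thresholds, rule for named genes and all alternatives but those said to be added. For each split, the spots of a section or the epithelial cells of a library were ranked by score into 3 parts, and the highest and lowest parts were summed per tumour. The splits ranked 2176 spots and 4296 cells. Scores are continuous: 338 spots in the stress split, 371 in the cancer epithelium split and 662 cells lay within 0.1 SD of a bound between parts. Genes of the list that made the split were left out of its test.

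The sums were tested with edgeR 4.0.16 (quasi-likelihood, TMM, its filter on low counts, tumour as a block), Benjamini-Hochberg adjusted over all genes tested, and with DESeq2 1.42.0 as an alternative. The block is the tumour, since both sums of a tumour come from 1 donor. Deviations of a tumour's 2 sums from the group means correlated at 0.57 to 0.741 in the stress split, 0.471 to 0.643 in the cancer epithelium split and 0.795 to 0.893 in the cells. Lists were tested with camera (preset and estimated correlation) and fry in limma 3.58.1. fry tests whether a list's genes move one way on balance and does not compare them with other genes. Camera called fewer lists with an estimated correlation, so member counts are given first. DESeq2's size factors in edgeR changed no list's sign. On simulated data, changed genes were drawn only among those with a mean of at least 32 CPM, so recovery of lower genes was not measured. Of these changed genes, edgeR recovered 100% of those changed 4-fold in each split. Of genes changed by 1 on the log2 scale it recovered 60% in the ST stress split (7990 genes run), 58% in the cancer epithelium split (8074) and 97% in the cells (10681), with 3.03%, 7.60% and 3.43% unchanged genes among those called.

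The rule for named genes took, among genes past an adjusted p of 0.05 with a mean log2 CPM of at least 5 and the same direction in every tumour, the 14 with the largest rise and the 10 with the largest fall, without ribosomal protein, mitochondrial and sex-linked genes, and up to 4 members per list by size of change. That a tumour with no counts of a gene gives it no direction was settled after a first look at the values. For the 2 cancer clones of A, the 12 genes with the largest ratio each way among 6274 with at least 30 counts were named, with 0 counts set to 3. Ratios have exact counting intervals at 95%.

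Pairs of lists were scored over spots with Spearman's rho per section, averaged per tumour, and tested with a two-sided exact sign-flip permutation test, adjusted over the 12 pairs. Random lists were matched on mean expression (1000 per pair, 20 per split, 10000 for clones and regions). Those for pairs and splits were drawn from genes outside all the fixed lists, without ribosomal protein genes. They were not matched on how far their genes vary together.

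inDrop cells had at least 1000 counts and at most 20% mitochondrial counts. Of 5820 cells, 72 called as doublets by Scrublet within scanpy (1.24%) were removed, leaving 5748. Each tumour was clustered alone with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 components, 15 neighbours, resolution 1). Markers of each class were fixed beforehand, and the scoring that names a cluster from them was settled after several looks at the clusters. Clusters below it stayed unnamed. Shares have Clopper-Pearson intervals at 95%. The levels of lists in the inDrop epithelium against the ST tissue were added after the splits had been seen.

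Regions of A and B were Leiden clusters of spots over the sections of a tumour (20 components, resolution 1). For each annotated population the 50 genes with the largest fold over the other populations were set against random lists in each region. Red blood cells of B (3 cells) gave too few genes and were left out. Regions are described by the 5 genes with the largest fold among those with at least 100 counts. Mitochondrial, sex-linked and date-named genes are not reported, nor is 1 result of the stress split of the cells, and no test was made between tumours. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.

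Alternatives tried were spot and cell minimums of 200, 500, 1000 or 2000 counts, 4 parts in place of 3, the score as a share of counts or residual on the fibroblast score, first sections only, cells ranked within clusters, DESeq2, DESeq2's size factors, no filter on low counts, no block, each tumour, library or section left out, Pearson and partial correlation, a clustering resolution of 0.5, 100 genes per population, at least 100 counts per clone gene, and the median gene of a list in place of its sum.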

Results

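Pancreatic ductal adenocarcinoma, the common cancer of the exocrine pancreas, was measured with 2 assays in tissue that the labels assign to 7 tumours, A to G. In inDrop, single dissociated cells are barcoded in droplets and their transcripts counted. In spatial transcriptomics (ST), a tissue section is laid on an array of barcoded spots, each of which captures transcripts from a small patch of tissue. inDrop covered tumours A (6 libraries), B (3) and C (4), and ST covered A (3 sections), B (3), D, E, F and G (1 each). An inDrop library held 826684 to 4282966 counts, and the libraries of a tumour summed to 9493239 counts over 12000 barcodes in A, 8698480 over 7000 in B and 4722173 over 8000 in C. An ST section held 269709 to 1404785 counts, and the sections of a tumour summed to 1918485 counts in A, 1085487 in B, 1404785 in D, 1038383 in E, 371862 in F and 612996 in G. The table held for F lists only the first part of the genes (5757), so F enters only where that is said. Tumours are the replicates, and sections or libraries of a tumour are summed or averaged and not counted as further replicates. Sections of a tumour can differ in the tissue they hold. Intervals given for a single tumour cover counting error only.

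The first comparison asks how the tissue of the tumours differs in its exocrine, endocrine, stromal and immune parts, from the ST counts, scaled to the tumour's total (CPM), of 31 fixed gene lists in A, B, D, E and G. With 1 tumour per value, no test between tumours was made. Genes of acinar cells, which make the digestive enzymes, spanned the widest range, from 68.5 CPM in E to 37632 in A, a ratio of 549.6. The level of A rests on its first section, which stood at 72186 CPM beside 136 and 87.4 CPM in the others, and the sections of B stood at 2891, 30319 and 575 CPM. Endocrine genes, those of the islet hormones and granules, ran from 87.6 CPM in B to 11314 in E. Genes of gut epithelium ran from 35.9 CPM in G to 3232 in D. The classical PDAC list, which marks the differentiated epithelial subtype, ran from 335 CPM in G to 13954 in D, and the basal-like PDAC list, which marks the squamous-leaning subtype, from 283 in G to 5519.6 in A (2556, 5889.7 and 15036 by section). Cancer epithelium genes ran from 1223 CPM in G to 13111 in A and ductal genes from 1922 in G to 18819 in A, so G held the least of all 5 epithelial lists named here.

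Of stromal lists, fibroblast genes, mostly collagens and other matrix genes, ran from 10100.3 CPM in A to 26950.4 in G, and inflammatory fibroblast genes, secreted chemokines and complement among them, from 2157 in D to 13084 in G. Myofibroblast genes ran from 5450.2 CPM in A to 12292 in B, pericyte and smooth muscle genes from 530.0 in A to 3730.1 in B, endothelial genes from 948 in A to 3084 in G, Schwann cell genes from 71.3 in D to 173 in G, and adipocyte genes from 24.5 in A to 140.5 in G. Among immune lists, T and NK genes ran from 91.9 CPM in D to 449 in G, B cell genes from 13.6 in A to 77.0 in D, plasma cell genes from 47.5 in A to 480.3 in D, macrophage and monocyte genes from 1857 in A to 4159.9 in G, mast cell genes from 82.0 in D to 833 in E, dendritic genes from 88.2 in G to 171 in B and plasmacytoid dendritic genes from 112 in D to 243 in G. In B the pericyte and smooth muscle level was carried by section 2, at 8631 CPM beside 1517 and 3073 in the others. The level of A in that list was 344 CPM without section 1. Dendritic genes of B stood at 115 CPM without section 3, which left E the highest. Macrophage and monocyte genes of A stood at 1230 CPM without its section 1. Those of B stood at 5376 CPM without its section 1, which made B the highest. In A, sections 2 and 3 lay far below section 1 in inflammatory fibroblast genes (891 and 825 against 4458 CPM), T and NK genes (71.1 and 66.4 against 181) and adipocyte genes (4.74 and 6.99 against 42.1), so which tumour is lowest depends on the section. Red blood cell genes ran from 17.5 CPM in B to 288 in D and tuft cell genes from 15 in D to 48.0 in B.

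Of the process lists, stress-response genes, the immediate-early and heat-shock genes, ran from 6208 CPM in B to 10981 in E, a ratio of 1.77, and genes of the unfolded protein response from 2894 in G to 4784 in D, a ratio of 1.65. Genes of the epithelial-mesenchymal transition (EMT) ran from 5707 CPM in A (8063 without section 1, which left B the lowest) to 11052 in E, hypoxia genes from 2322 in G to 5765 in D, MHC class II genes from 2869 in D to 8281 in E (in A 4885, 594 and 1153 by section), NF-kB targets from 753 in G to 2438 in D, proliferation genes from 144 in G to 564 in D and type I interferon genes from 989.8 in G to 5029 in A. The sections of A stood at 4107, 3670.0 and 11252 CPM in the last list and B at 4262, so the ratio of 5.08 rests on section 3 of A. A ratio of at least 5 between the highest and the lowest tumour was reached by 15 of the 31 lists. Leaving out each section of A and of B in turn, added after seeing the data, gave 14 to 16 such lists. It changed the highest or the lowest tumour in 16 lists: acinar, endothelial, inflammatory fibroblast, adipocyte, T and NK, B cell, macrophage and monocyte, dendritic, plasmacytoid dendritic, red blood cell, stress-response, EMT, hypoxia, MHC class II, proliferation and type I interferon.

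**Figure D1:**
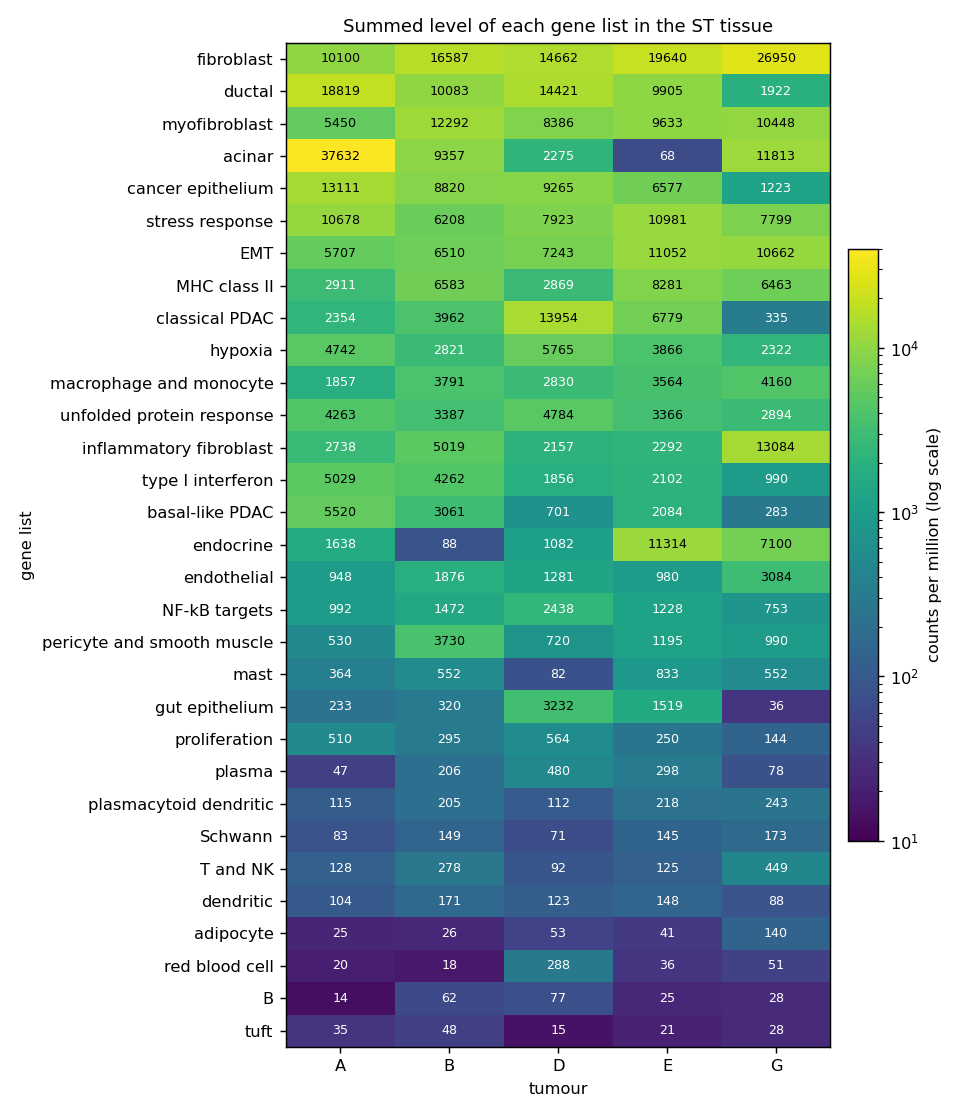
Summed level of each fixed gene list (vertical axis) in the ST tissue of 5 tumours (horizontal axis), in CPM on a log colour scale with the value printed in each cell. Acinar genes run from 68.5 CPM in E to 37632 in A, and stress-response genes from 6208 in B to 10981 in E.

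The inDrop libraries ask which cell classes each tumour gave after dissociation. After filtering, 2053 cells of A, 2480 of B and 1215 of C were clustered. Cells of the ductal or cancer-like class made up 78.3% of A (exact binomial interval 76.4 to 80.0; 73.4 to 81.5 over libraries), 66.3% of B (64.4 to 68.2; 52.1 to 85 over libraries) and 87.6% of C (85.6 to 89.4; 82.8 to 89.9 over libraries). Without library 3 of B that share was 80.1%. Macrophage and monocyte-like cells were 4.97% of A and 2.94% of B, T and NK-like cells 3.02% of A, tuft-like cells 2.24% of A, endothelial-like cells 6.77% of B and 0.536% of A, and fibroblast-like cells 3.13% of C. Acinar-like cells were 0.731% of A, 0.242% of B and 0.412% of C. Mast-like cells were 0.682% of A and 0.323% of B, and plasmacytoid dendritic-like and red blood cell-like cells 0.487% and 0.731% of A. Clusters given no name held 8.33% of A, 23.4% of B (4.93 to 39.2 over libraries) and 8.89% of C. In B, 409 of the 448 cells of the largest of these clusters came from library 3, and without that library the unnamed share was 8.04%. A cell had to pass a minimum of 1000 counts. With 500, T and NK-like cells were 1.5% of A, and no cluster of C was named fibroblast-like. At a resolution of 0.5 no cluster of B was named macrophage and monocyte-like. Cells of a class can lie in unnamed clusters, so a lost name does not mean lost cells.

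In the submitters' own annotation of 1926 cells of A, the ductal cells called high in CRISP3 or centroacinar-like were 27.5%, terminal ductal-like cells 18.2%, MHC class II ductal cells 14.9%, the ductal cells called high in APOL1 or hypoxic 11.2%, and cancer clones A and B 6.54% and 8.83%. Of the 1733 annotated cells of B, terminal ductal-like cells were 42.5%, the single cancer clone 19.6%, MHC class II ductal cells 12.2%, endothelial cells 9.17% and the CRISP3-high ductal cells 8.77%.

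Epithelial cells of the 3 dissociated tumours differed in several lists. Gut epithelium genes stood at 5796 CPM (exact Poisson interval 5707 to 5887) in C, against 697 in A and 770.3 in B. MHC class II genes, which present antigen to helper T cells, stood at 459 CPM (434 to 485) in C, against 4041 in A and 7761 in B. EMT genes stood at 551 CPM in A, 100.1 in B and 45.3 in C, and fibroblast genes at 249.9 in A, 72.5 in B and 22.3 in C. Type I interferon genes stood at 7103 CPM in A, 5085 in B and 2665 in C, and proliferation genes at 409.7 in A, 782 in B and 422 in C. The class was held by 9 clusters in A, 8 in B and 9 in C, found in each tumour alone. Tumours were not tested against each other, since each is 1 donor.

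For A and B, the epithelial cells were set beside the ST tissue of the same tumour over 19251 shared genes. Stress-response genes were 2.15 times (2.12 to 2.19) as high in the dissociated epithelium as in the tissue in A and 2.29 times (2.23 to 2.35) in B. NF-kB targets were 3.92 times as high in A and 2.5 times in B, and classical PDAC genes 7.07 times in A and 8.99 times in B. Hypoxia genes stood at 0.946 times in A and 1.27 times in B, and basal-like PDAC genes at 0.641 times in A and 1.0 times in B. The basal-like level in the tissue of A was 8737 CPM without section 1 and 3850 without section 3, beside 5520 over all sections, so that ratio depends on the section. Fibroblast genes were 35.7 times as high in the tissue of A and 193 times in that of B. Acinar genes were 320.4 times as high in the tissue of A and 197 times in that of B, but these ratios rest on single sections. In A, section 1 stood at 72186 CPM and the others at 136 and 87.4, beside 119 in the cells. Without section 2 the tissue of B stood at 2117 CPM, beside 48.0 in its cells. The tissue holds all its cells, the cells are epithelium alone, and the 2 assays differ. These ratios can therefore mix composition, dissociation and assay, which no test separated.

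What goes with cancer epithelium inside the tissue was asked by splitting the spots of each section by a 17-gene score of cancer epithelium (mucins, CEACAMs and trefoil factors among them) and comparing the highest with the lowest of 3 parts, tumour by tumour. Of 8656 genes tested, 528 changed at an adjusted p of 0.05 in edgeR, 336 higher and 192 lower (n = 5 tumours). At an unadjusted p of 0.05 the count was 1597, and DESeq2 called 293, of which 290 were shared. Without tumour D the count was 241 and without E 244. ARL14, a small GTPase of vesicle traffic, rose by a log2 fold change of 2.56 ± 0.41 (SE, n = 5; adjusted p = 8.4e-04). DUOX2, the epithelial oxidase that makes hydrogen peroxide, rose by 2.24 ± 0.27 (adjusted p = 1.6e-04), and its maturation factor DUOXA2 by 1.95 ± 0.29. The transcription factor KLF5 of proliferating gut epithelium rose by 2.01 ± 0.25 (adjusted p = 1.6e-04). PSCA, a surface antigen raised in pancreatic cancer, rose by 2.15 ± 0.46, the tight junction gene CLDN23 by 2.25 ± 0.46, the stratified-epithelium keratin KRT15 by 2.14 ± 0.37 and TRIM15, a ubiquitin ligase of focal adhesions, by 2.28 ± 0.41. TM4SF4, a tetraspanin-related membrane protein, rose by 2.08 ± 0.31, and MAL2, of apical membrane transport, by 1.97 ± 0.27. The brush-border protocadherin CDHR2 rose by 2.01 ± 0.33 and its myosin partner MYO7B by 1.90 ± 0.36. ERN2, the stress sensor of mucous cells, rose by 1.98 ± 0.26, and DKK1, a secreted inhibitor of Wnt signalling, by 1.93 ± 0.36. These 14 genes were higher in 5 of 5 tumours. The rule for named genes requires a shared direction in every tumour, here and for the named falls below. Leaving out 1 tumour ended the call of PSCA (adjusted p = 0.056 without A), TRIM15 (0.053 without D), CLDN23 and KRT15 (0.060 and 0.12 without E).

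Lower in cancer-rich spots of 5 of 5 tumours were the carboxypeptidase CPA5, which fell by 2.93 ± 0.46 (SE, n = 5; adjusted p = 6.9e-04), the chymotrypsinogen CTRB1 by 2.38 ± 0.46 and the amylases AMY2A and AMY1A, with log2 fold changes of -2.31 ± 0.48 and -2.08 ± 0.53. Reads can be split between near-identical copies, so AMY1A, AMY2A and CTRB1 are uncertain as single genes. The lipase CEL fell by 2.2 ± 0.45. DESeq2 did not call CEL (adjusted p = 0.14) or AMY1A (adjusted p = 0.088). In E the direction of CTRB1, CEL and AMY2A rests on few reads, since the 16 acinar genes together had 71 counts there. Acinar genes of A had 72029 counts in section 1, 86 in section 2 and 25 in section 3. The rho of the cancer epithelium and acinar scores over spots was 0.0915 in E and negative in the other tumours. C7, a complement gene of stromal cells, fell by 1.85 ± 0.33 (adjusted p = 0.0016), LMOD1, an actin nucleator of smooth muscle, by 1.77 ± 0.31, and SYNPO2, an actin-bundling gene of muscle, by 1.93 ± 0.40. MAP1B, a microtubule gene of nerve, fell by 1.69 ± 0.31 and SCG5, a secretory granule gene of endocrine cells, by 1.67 ± 0.34. Leaving out 1 tumour ended the call of AMY2A, AMY1A and SYNPO2 (adjusted p = 0.11, 0.36 and 0.27 without B) and of SCG5 (0.050 without D).

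Lists were read by their members, since none passed in camera with an estimated correlation. The score itself holds the classical PDAC genes CEACAM6, TFF1, TFF2, AGR2 and TSPAN8 and the basal-like gene KRT17, which were not tested here. Spots ranked by epithelial genes also differ in cell content. A rise of other epithelial genes and a fall of genes of other cells can follow from that ranking. Of 15 classical PDAC genes tested, 11 rose and none fell (14 adjusted over the list alone), with ANXA10 at 2.12 ± 0.47, CLRN3 at 1.97 ± 0.50, AGR3 at 1.95 ± 0.55 and MYO1A at 1.60 ± 0.45 (adjusted p = 0.101 for the list in camera with an estimated correlation). Of 11 basal-like PDAC genes, 7 rose (9 adjusted over the list alone), among them SPRR3 at 2.58 ± 0.57, TNS4 at 1.73 ± 0.27 and SPRR1B at 1.69 ± 0.47 (adjusted p = 0.101 with an estimated correlation). SPRR3 and SPRR1B had a direction in 3 tumours only. Of 12 ductal genes, 8 rose, MUC1 at 1.69 ± 0.21, KRT19 at 1.5 ± 0.21 and EPCAM at 1.47 ± 0.25 among them, and AMBP fell by 1.47 ± 0.33 in 3 of 5 tumours (10 up and 1 down adjusted over the list alone; adjusted p = 0.108 with an estimated correlation). Hypoxia genes rose in 2 of 14 cases, the carbonic anhydrase CA9 at 1.22 ± 0.28 and the glucose transporter SLC2A1 at 1.03 ± 0.22 (4 adjusted over the list alone; adjusted p = 0.319 with an estimated correlation). Of 4 gut epithelium genes, ANPEP rose at 1.10 ± 0.32 (4 adjusted over the list alone; adjusted p = 0.243 with an estimated correlation). Stress-response genes moved both ways: FOS rose by 0.99 ± 0.23, GADD45B fell by 0.81 ± 0.23, and 24 of 26 did not pass (5 up and 1 down adjusted over the list alone; adjusted p = 0.469 with an estimated correlation). BIRC3 alone of 13 NF-kB targets rose, by 0.96 ± 0.28 (3 up and 1 down adjusted over the list alone). No member passed among 13 type I interferon genes, 9 proliferation genes and 11 genes of the unfolded protein response. The median of the last list was -0.01 and its mean 0.01. Several of these calls ended when 1 tumour was left out, and a fit on fewer tumours also has less power. Without D, the adjusted p was 0.062 for ANXA10, 0.084 for CLRN3, 0.084 for AMBP, 0.11 for CA9, 0.12 for ANPEP, 0.13 for FOS, 0.079 for GADD45B and 0.16 for BIRC3. Without E, it was 0.23 for MYO1A, 0.093 for SPRR1B, 0.12 for CLRN3, 0.084 for SLC2A1, 0.096 for CA9, 0.20 for ANPEP, 0.097 for FOS, 0.14 for GADD45B and 0.34 for BIRC3. Without A, CLRN3 (0.078), AMBP (0.17) and BIRC3 (0.063) lost their calls, without B, ANPEP (0.27) and GADD45B (0.14) did, and without G, BIRC3 (0.054) did.

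In the same spots, 15 of 16 acinar genes fell (16 adjusted over the list alone), with CELA2A at -3.07 ± 0.44, SYCN at -2.98 ± 0.51 and PLA2G1B at -2.93 ± 0.55 (adjusted p = 0.153 with an estimated correlation). These 3 had few counts in E and fell in at most 4 tumours. In A, nearly all acinar counts came from section 1. Of 9 endocrine genes, 3 fell, PPY at -2.04 ± 0.44, SCG5 and INS (6 adjusted over the list alone; adjusted p = 0.246 with an estimated correlation). Fibroblast genes fell in 6 of 11 cases, LUM at -1.0 ± 0.20, FBLN1 at -0.98 ± 0.20 and DCN at -0.94 ± 0.22 (10 adjusted over the list alone; adjusted p = 0.125 with an estimated correlation). Of 19 inflammatory fibroblast genes, 6 fell, the monocyte attractant CCL2 at -2.29 ± 0.59 among them (12 adjusted over the list alone; adjusted p = 0.101 with an estimated correlation). Of 14 myofibroblast genes, 4 fell, SFRP4 at -1.44 ± 0.29, SFRP2 at -1.15 ± 0.22, TPM2 at -0.84 ± 0.22 and ACTA2 (8 adjusted over the list alone; adjusted p = 0.246 with an estimated correlation). Endothelial genes fell in 4 of 9 cases, CDH5 at -1.72 ± 0.48, CLDN5 at -1.18 ± 0.26, PECAM1 at -1.02 ± 0.22 and VWF (9 adjusted over the list alone; adjusted p = 0.101 with an estimated correlation). INS, ACTA2 and VWF were named after their values were seen. Without A, the adjusted p was 0.54 for PPY, 0.064 for CCL2 and 0.074 for CDH5. Without B, it was 0.11 for TPM2. Without D, it was 0.097 for DCN, 0.13 for CCL2, 0.14 for CDH5, 0.055 for PECAM1 and 0.12 for TPM2. Without E, it was 0.053 for PPY, 0.10 for CCL2, 0.056 for CDH5 and 0.078 for TPM2, and without G it was 0.072 for TPM2.

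Of 8 pericyte and smooth muscle genes, 3 fell, DES at -1.93 ± 0.32, LMOD1 and CNN1 at -1.26 ± 0.26 (5 adjusted over the list alone; adjusted p = 0.202 with an estimated correlation). Macrophage and monocyte genes fell in 3 of 12 cases, AIF1 at -1.12 ± 0.28, C1QB at -0.90 ± 0.22 and C1QC (9 adjusted over the list alone; adjusted p = 0.101 with an estimated correlation). Of 11 MHC class II genes, 3 fell, HLA-DRB1 at -0.86 ± 0.22, HLA-DRA at -0.85 ± 0.24 and HLA-DPA1 (11 adjusted over the list alone; adjusted p = 0.246 with an estimated correlation). MZB1 at -1.74 ± 0.39 and JCHAIN at -1.61 ± 0.28 fell among 4 plasma cell genes (3 adjusted over the list alone; adjusted p = 0.147 with an estimated correlation). Of 12 EMT genes, 3 fell, SPARC at -0.99 ± 0.20, VIM and MMP2 (6 adjusted over the list alone; adjusted p = 0.241 with an estimated correlation). No member passed among 5 T and NK, 4 mast cell, 3 red blood cell, 3 plasmacytoid dendritic and 3 Schwann cell genes. Adjusted over the list alone, 3 of 3 red blood cell genes fell (median -1.53). Camera called the red blood cell and mast cell lists with its preset correlation (adjusted p = 0.021 and 0.036) and not with an estimated one (adjusted p = 0.291 and 0.322). C1QC, HLA-DPA1, VIM and MMP2 were named after their values were seen. Without D, the adjusted p was 0.087 for AIF1, 0.068 for C1QB, 0.12 for HLA-DRB1, 0.19 for HLA-DRA, 0.20 for MZB1 and 0.051 for SPARC. Without E, it was 0.10 for AIF1, 0.073 for C1QB, 0.093 for HLA-DRB1, 0.15 for HLA-DRA and 0.066 for MZB1. Without A, AIF1 (0.052), HLA-DRB1 (0.064) and HLA-DRA (0.096) lost their calls, and without B, DES (0.11) and CNN1 (0.099) did. With its preset correlation camera called 19 of 26 lists, 6 up and 13 down. With an estimated correlation it called 0, with 8 at an unadjusted p of 0.05, and fry called 7 (lowest adjusted p = 0.021).

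**Figure D2:**
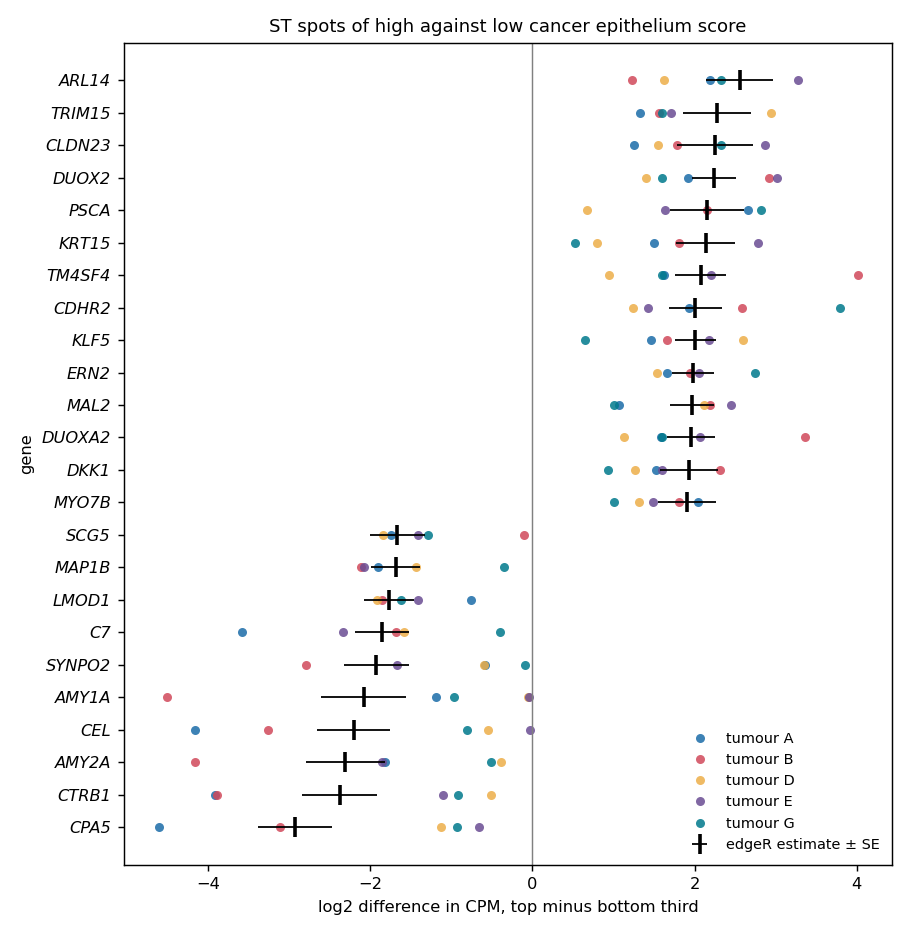
Log2 fold change of the named genes between ST spots of high and low cancer epithelium score (horizontal axis), with 1 point per tumour and the fitted value with its SE. Genes named only by list are not shown. Of those shown, ARL14 is the highest at 2.56 ± 0.41 and CPA5 the lowest at -2.93 ± 0.46.

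How gene programmes share the tissue was also asked as Spearman's rho between the scores of 12 pairs of lists over spots, averaged per tumour. Where n = 6, tumour F is included. Its scores rest on the few list genes that its table of 5757 genes holds. Cancer epithelium and inflammatory fibroblast genes had the lowest value, a mean rho of -0.295 ± 0.098 (SD, n = 6 tumours), negative in 6 of 6. Cancer epithelium was negative in 6 of 6 tumours also with myofibroblast genes (-0.23 ± 0.173) and with macrophage and monocyte genes (-0.181 ± 0.0775), and positive in 6 of 6 with stress-response genes (0.121 ± 0.106, with B at 0.00307). Each of these 4 had an exact sign-flip p = 0.031 (n = 6, two-sided), the smallest that 6 tumours allow, and an adjusted p = 0.094 over the 12 pairs, so none passed. Without F, the 5 tumours left allow no exact p below 0.0625. Sections of a tumour did not all go the same way. Cancer epithelium with myofibroblast genes stood at 0.227 in section 1 of A, against -0.367 in section 2 and -0.106 in section 3. With macrophage and monocyte genes it stood at 0.0355 in section 3 of A, and with stress-response genes at -0.0632 in section 2 of B. Not all of these 4 pairs held in other settings. As a partial correlation the pair with myofibroblast genes stood at -0.072, positive in 2 of 6 tumours (exact p = 0.219, n = 6). Stress response with cancer epithelium was positive in 5 of 6 tumours at 1000 counts per spot (exact p = 0.094, n = 6), and in 4 of 6 with the share score or Pearson's r (exact p = 0.125, n = 6). MHC class II genes went with T and NK genes at 0.17 ± 0.0456 in 5 of 5 tumours (exact p = 0.0625, adjusted p = 0.107, n = 5, again the smallest possible). The T and NK score rests on few counts, from 19 over section 3 of A to 275 over the section of G. Stress-response genes went with NF-kB targets at 0.0922 ± 0.0691 and cancer epithelium with hypoxia genes at 0.14 ± 0.156, each positive in 5 of 6 tumours (exact p = 0.0625, adjusted p = 0.107, n = 6). Pairs were also set against 1000 random second lists matched on expression over 5 tumours. Below all of them lay 3 pairs: cancer epithelium with inflammatory fibroblast, myofibroblast, and macrophage and monocyte genes. Above all of them lay 4: stress response with cancer epithelium, NF-kB targets and hypoxia, and MHC class II with T and NK genes. The random lists held only genes outside the fixed lists. Genes of a cell type or process can vary together, and such lists may lie outside that range for this reason alone. The comparison therefore cannot set these pairs apart from other pairs of marker lists. The remaining pairs were cancer epithelium with acinar genes at -0.0852 ± 0.108 (exact p = 0.094, adjusted p = 0.141, n = 6), and stress response with hypoxia at 0.0672 ± 0.0918 (exact p = 0.156, n = 6), with myofibroblast at -0.0408 ± 0.0876 (exact p = 0.344, n = 6), with macrophage and monocyte at -0.0175 ± 0.0381 (exact p = 0.281, n = 6) and with inflammatory fibroblast genes at -0.0036 ± 0.168 (exact p = 0.938, n = 6). In this last pair, G at 0.294 and B at 0.103 were positive and the others negative.

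**Figure D3:**
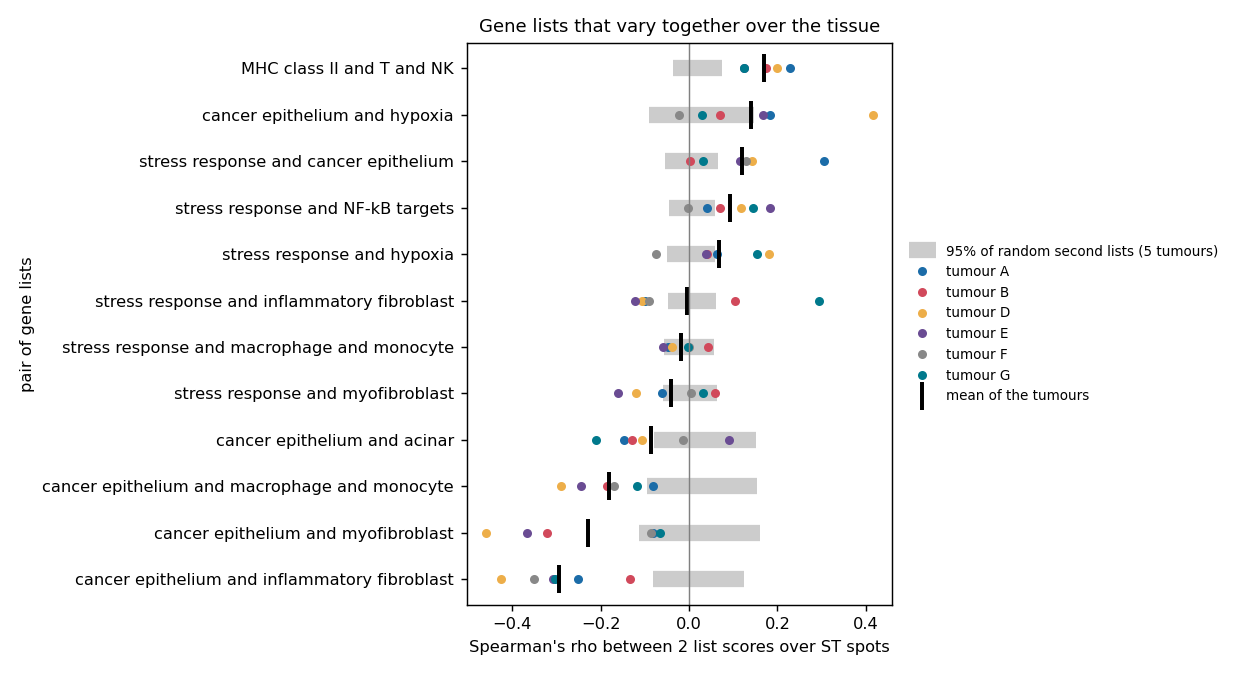
Spearman's rho between the scores of each pair of gene lists over ST spots (horizontal axis), with 1 point per tumour, the mean of the tumours as a bar and 95% of random second lists as a grey band. Cancer epithelium with inflammatory fibroblast genes has the lowest mean, -0.295, outside the band.

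The stress-response programme in tissue, where no cell was dissociated, was asked by splitting spots by the 26-gene stress score. Of 8463 genes, 2 changed in edgeR (n = 5 tumours), with 500 at an unadjusted p of 0.05. PPY, the hormone of islet PP cells, fell by 2.07 ± 0.26 (SE; adjusted p = 3.9e-04, lower in 5 of 5 tumours), and DESeq2 called this gene alone. Without tumour A it had an adjusted p of 0.999. The count was 1 without A, 4 without E and 31 without G. PI16, a marker of a fibroblast reserve, named after its values were seen, rose by 2.43 ± 0.39 (adjusted p = 0.012, higher in 4 of 5 tumours, none lower), and DESeq2 did not call it (adjusted p = 0.14). Of 20 random lists matched on expression and used in place of the stress list, 16 called at least as many genes. Of 16 acinar genes none passed (16 down adjusted over the list alone, median -1.40, with SYCN at -1.77 ± 0.57), and of 9 endocrine genes PPY passed (3 down adjusted over the list alone). Cancer epithelium genes stood at a median of 0.36 (5 of 17 up adjusted over the list alone, CLDN18 at 0.55 ± 0.24 in 5 of 5 tumours) and hypoxia genes at 0.24 (none of 14 adjusted over the list alone, ADM at 1.16 ± 0.40 in 5 of 5). Camera called these 4 lists of 25 with its preset correlation and none with an estimated one (adjusted p = 0.45 for each, with 1 list at an unadjusted p of 0.05), and fry called 0 (lowest adjusted p = 0.399). For inflammatory fibroblast genes the median was -0.02 and the mean 0.18, and for plasmacytoid dendritic genes the median and mean were above 0 and the test below.

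The same score in dissociated epithelial cells asks which genes go with stress among the cells of 1 class, which pools several clusters of ductal and cancer cells. In A, B and C, 148 of 10846 genes changed in edgeR between the highest and the lowest of 3 parts of the cells, 110 higher and 38 lower (n = 3 tumours), with 1342 at an unadjusted p of 0.05. DESeq2 called 78, all shared, and without tumour B edgeR called 353. CXCL2, a neutrophil attractant, rose by 1.99 ± 0.13 (SE, n = 3; adjusted p = 1.6e-06). SOCS3, which damps cytokine signalling, rose by 1.84 ± 0.14, PPP1R15A, which restarts translation after stress, by 1.86 ± 0.17, and CSRNP1, an immediate-early factor, by 1.78 ± 0.14. KLF2, a shear and stress factor, rose by 1.72 ± 0.12, RHOB, a stress-induced GTPase, by 1.67 ± 0.13, and the matricellular gene CYR61 by 1.67 ± 0.27. ADM, a hypoxia-induced peptide, rose by 1.67 ± 0.15 and the hypoxia target ANKRD37 by 1.59 ± 0.20. NR4A2, an immediate-early nuclear receptor, rose by 1.45 ± 0.22, the kinase PLK3 by 1.41 ± 0.17, the pseudokinase TRIB1 by 1.40 ± 0.14, the death gene PMAIP1 by 1.36 ± 0.16 and HBEGF, a ligand of the EGF receptor, by 1.36 ± 0.13. Each of these 14 was higher in 3 of 3 tumours, which the rule for named genes requires, with adjusted p up to 0.0040. Cells ranked by immediate-early and heat-shock genes can also differ in related genes outside the score. A rise of such genes can follow from that ranking.

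The stratified-epithelium keratins KRT6A and KRT6B fell by 1.70 ± 0.21 each (SE, n = 3; adjusted p = 4.9e-04 and 6.3e-04), and KRT16 fell by 1.06 ± 0.16. KRT6A, KRT6B and KRT16 share sequence with close copies and are uncertain as single genes. LY6D, a squamous surface marker, fell by 1.44 ± 0.21, the gap junction gene GJA1 by 1.22 ± 0.24, the urokinase gene PLAU by 1.42 ± 0.30 and its inhibitor SERPINB2 by 1.36 ± 0.31. SERPINB7, a further serpin, fell by 1.19 ± 0.22, the decoy receptor IL1R2 by 1.05 ± 0.23 and the membrane protein DCBLD2 by 0.99 ± 0.23. Each was lower in 3 of 3 tumours, as the rule requires. DESeq2 did not call PLAU, SERPINB2, GJA1, SERPINB7, IL1R2 or DCBLD2. Each of these 6 calls also ended when 1 tumour was left out: the adjusted p was 0.28 for PLAU, 0.53 for GJA1 and 0.69 for DCBLD2 without A, and 0.26 for SERPINB2, 0.80 for SERPINB7 and 0.19 for IL1R2 without C.

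High and low cells lay unevenly over the clusters of the class. In A, the cluster led by CXCL2, CXCL1 and CXCL3 gave 117 of its 261 cells to the high part and 65 to the low, and the cluster led by LY6D, COL6A1 and S100A4 gave 28 of 194 to the high part and 105 to the low. With cells ranked within each cluster, an alternative added after seeing the data, 167 genes changed in edgeR, 114 higher and 53 lower, with 94 shared with the 148. The 14 genes named first as higher kept their calls, CXCL2 at 1.51 and ADM at 0.79 among them. Of the genes named as lower, PLAU (-0.57, adjusted p = 0.037) and SERPINB7 (-1.16, 0.0019) kept theirs. KRT6A stood at -0.97 (adjusted p = 0.10), KRT6B at -0.80 (0.20), SERPINB2 at -0.84 (0.22), GJA1 at -0.40 (0.54), IL1R2 at -0.36 (0.51), DCBLD2 at -0.32 (0.54) and KRT16 at -0.07 (0.94), while LY6D stood at 0.49 (0.49). Without the differences between clusters the calls of these 8 genes ended.

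By list, 6 of 14 NF-kB targets rose (8 adjusted over the list alone), with CXCL3 at 1.31 ± 0.18, CXCL8 at 1.15 ± 0.20 and NFKBIA at 1.04 ± 0.13 beside CXCL2 (adjusted p = 0.378 with an estimated correlation). Of 15 hypoxia genes, ADM and VEGFA (0.92 ± 0.12) rose (7 adjusted over the list alone; adjusted p = 0.378 with an estimated correlation). Of 13 ductal genes, CLDN4 rose by 0.91 ± 0.12 and ELF3 by 0.80 ± 0.11 (adjusted p = 0.378 with an estimated correlation). Of 12 genes of the unfolded protein response, DDIT3 rose by 1.15 ± 0.19 and HERPUD1 by 0.55 ± 0.12, while the list's median was -0.09 and its mean 0.08. Of 18 basal-like PDAC genes, CST6, KRT6A and LY6D fell, CST6 by 2.30 ± 0.48 in 2 of 3 tumours, and AREG, named after its values were seen, rose by 0.78 (6 down and 1 up adjusted over the list alone; adjusted p = 0.46 with an estimated correlation). CXCL14 fell by 2.37 ± 0.42 and INHBA by 3.60 ± 0.60, each in fewer than 3 tumours. The call of HERPUD1 ended without A (adjusted p = 0.060), B (0.058) or C (0.11). DESeq2 did not call CXCL8 (adjusted p = 0.36), DDIT3 (0.051) or HERPUD1 (0.29). For the cancer epithelium list the median was -0.18 (adjusted p = 0.012 in camera with its preset correlation and 0.460 with an estimated one). No member passed among 22 classical PDAC (median -0.13), 15 type I interferon (median 0.21, 1 up adjusted over the list alone), 15 proliferation (median -0.40, 2 down), 11 MHC class II (median 0.25) and 6 EMT genes (median -0.98, 3 down). Camera called these 5 with its preset correlation (adjusted p = 0.018, 0.0098, 2.2e-04, 6.9e-04 and 0.025). With an estimated one the adjusted p was 0.492 for proliferation and 0.509 for the others. No member passed among 3 fibroblast genes (3 down adjusted over the list alone, median -1.11) and 3 red blood cell genes (1 up, median 0.79) either. With its preset correlation camera called 11 of 17 lists, 6 up and 5 down. With an estimated correlation it called 0, with 2 at an unadjusted p of 0.05, and fry called 0 (lowest adjusted p = 0.219).

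**Figure D4:**
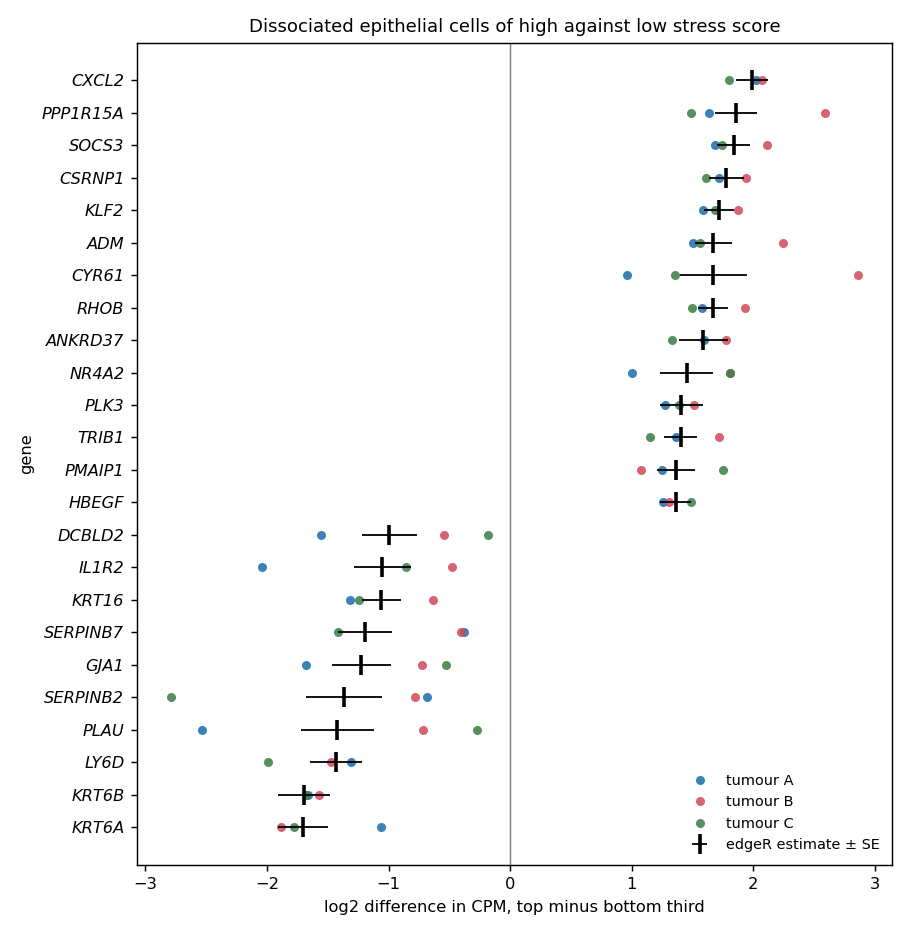
Log2 fold change of the named genes between inDrop epithelial cells of high and low stress-response score (horizontal axis), with 1 point per tumour and the fitted value with its SE. Genes named only by list are not shown. Of those shown, CXCL2 is the highest at 1.99 ± 0.13, and KRT6A and KRT6B are the lowest at -1.70 ± 0.21.

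Tumour A holds 2 annotated cancer populations, clone A (126 cells, 507977 counts) and clone B (170 cells, 597884 counts), and their sums were compared as 2 libraries, with no replicate check. Clone B held more mRNA of type I interferon genes, 3.61 times clone A's (exact interval 3.44 to 3.79, with 15 of 15 genes higher), of MHC class II genes, 2.88 times (2.58 to 3.21), and of EMT genes, 8.17 times (7.17 to 9.34). EMT genes had a median log2 ratio of 1.90 over the 5 of 12 genes with at least 30 counts. Fibroblast genes went the same way, at 117 counts against 24 (4.14 times, 2.65 to 6.72), while myofibroblast genes stood at 0.845 times (0.735 to 0.972). Clone A held more of hypoxia genes, 2.11 times (median log2 ratio of B to A -1.0), and of classical PDAC genes, 3.58 times (median -1.0, with 4 of 13 genes higher in B). Basal-like PDAC genes were 1.86 times as high in clone B (1.78 to 1.95, median 1.68). Inflammatory fibroblast genes were 1.78 times as high (1.54 to 2.08) by their sum, but only 5 of 20 had at least 30 counts, with 3 of the 5 higher in B and a median of 0.07, at percentile 61.2 of random lists. Stress-response genes were 1.08 times as high in clone B (1.05 to 1.11; median log2 ratio -0.07), NF-kB targets 1.11 times (1.03 to 1.20), ductal genes 1.16 times (1.12 to 1.20), proliferation genes 1.15 times (1.00 to 1.33), and genes of the unfolded protein response 0.924 times. Cancer epithelium genes were 1.21 times as high in clone A by their sum, while 10 of 17 were higher in clone B (median 0.17).

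Of single genes, clone B held MGP, a matrix inhibitor of calcification, at 382 counts against 0 (108 times with 0 set to 3 counts over the clone, and at least 87.6 times by the lower exact bound). TGFBR2, a receptor of TGF-beta, was 167 times as high (29.7 to 6644), the protease inhibitor A2ML1 109 times (19.2 to 4329), the interferon-induced SAMD9L 86.7 times (15.2 to 3456), the collagen chain COL6A2 83.3 times (28.2 to 406), the secreted MIA and the adhesion gene VCAM1 56.9 times each (15.5 to 475 and 9.87 to 2282), FAM198B, a Golgi protein, 48.4 times (8.35 to 1946), LY6D 41.4 times (25.3 to 72.7), the guidance cue SEMA3C 40.8 times (13.7 to 200.1), the synuclein SNCG 33.3 times (14 to 104) and the adaptor FYB1 31.4 times (10.5 to 155). Clone A held the collagenase MMP1 at 702 counts against 4, 207 times as high (80.3 to 760.2). The matrix proteoglycan VCAN was 132 times as high in clone A (23.2 to 5253), the elastase MMP12 121 times (21.3 to 4834), the amino acid transporter SLC6A20 95.3 times (16.6 to 3811), the pantetheinase VNN1 80.0 times (13.9 to 3207), the trypsin inhibitor SPINK1 56.3 times (1531 counts against 32), CA9 55.3 times (9.46 to 2231), the gap junction gene GJA1 39.7 times, the T cell ligand TNFSF9 37.7 times (6.29 to 1534) and the cornified-envelope gene SPRR3 33.8 times. SERPINB4 and SERPINB3, at 58.8 times (10.1 to 2370.3) and 50.0 times (13.4 to 419.7), are near-identical copies and uncertain as single genes.

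**Figure D5:**
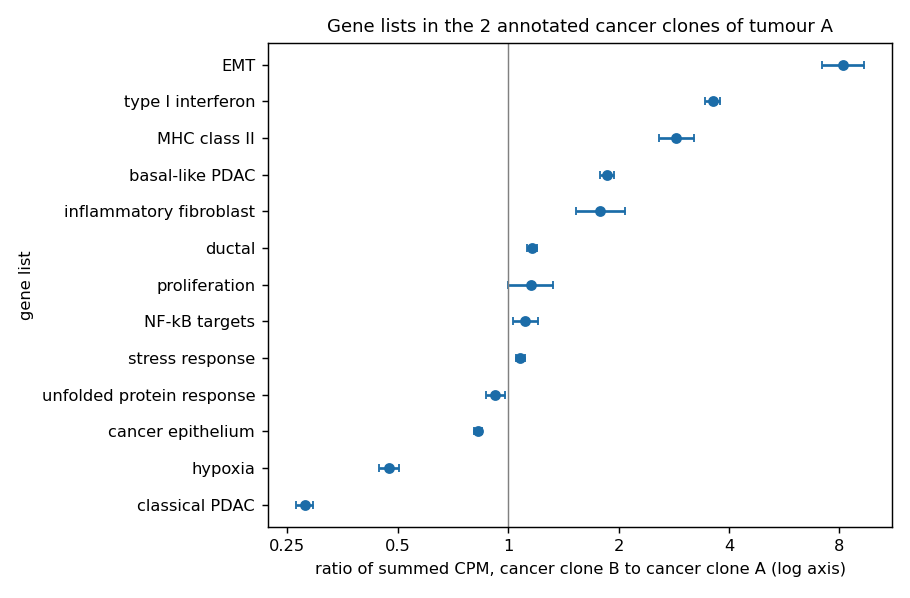
Ratio of summed CPM in cancer clone B to clone A of tumour A (log axis) for each gene list, with the exact 95% counting interval. EMT genes stand at 8.17, type I interferon genes at 3.61 and MHC class II genes at 2.88 times clone A, and classical PDAC genes 3.58 times as high in clone A.

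Where the annotated populations' genes lie was asked in the sections of A and of B. Spots of A fell into 7 regions at a resolution of 1, and into 5 at 0.5, where none was led by PPY or BEST1. Genes of the CRISP3-high ductal population were 3.01 times as high as in the other spots in a region of 143 spots (23.4% of 610, led by SCGB3A1, TFF3 and MUC5B), with MHC class II ductal genes at 1.37 times and T and NK genes at 1.26 times. Clone A genes were 2.28 times as high in a region of 113 spots (18.5%, led by HSPA1A, SLC6A14 and DKK1), with genes of the annotated fibroblasts, chosen from only 5 cells, at 1.46 times and hypoxic ductal genes at 1.33 times. Clone B genes were 2.37 times as high in another region of 71 spots (11.6%, led by SAA1, KRT16 and ISG15). Acinar genes were 5.33 times as high in a region of 43 spots (7.05%, led by CPB1, PNLIPRP1 and PRSS1), with myeloid dendritic genes of populations B and A at 2.23 and 2.00 times, and 2.02 times as high in a region of 45 spots (7.38%, led by PPY, CPA5 and PRSS2). Regions led by BEST1, CAVIN1 and RARRES2 (108 spots) and by CAPN8, NOTCH3 and APOL1 (87 spots) made up 17.7% and 14.3%. Each of these values lay at or above the 99th percentile of 10000 random lists. Of 140 pairs of region and population 29 did, beside 1.4 for 1% of the pairs, and in 2 of the 29 the ratio itself was below 1. Regions were made from the expression of the same spots, so 1.4 is not what chance gives for genes that vary together. Most spots of several regions came from 1 section, 141 of 143 in the first. Genes of myeloid dendritic populations B and A of this tumour were chosen from 33 and 12 cells, and its acinar genes from 13.

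In B, 552 spots fell into 10 regions at a resolution of 1. At 0.5 they fell into 4, led by SFRP2, SYNPO2, CRP and PNLIP, and none was led by C1QB, MMP11 or LYZ. The values below are those at a resolution of 1. Genes of myeloid dendritic cells (2.11 times), macrophages (1.99), monocytes (1.79) and mast cells (1.76) were each raised in a region of 114 spots (20.7%, led by C1QB, HLA-DRA and C1QA). They were chosen from 35, 9, 20 and 13 annotated cells, in that order. Genes shared between these lists were not counted, so the values may not be independent. Cancer clone genes were 1.25 times as high in a region of 67 spots (12.1%, led by MMP11, WFDC2 and IGFBP2), and endothelial genes 1.68 times in a region of 64 spots (11.6%, led by ACTG2, DES and CNN1). CRISP3-high ductal genes were 1.99 times and MHC class II ductal genes 1.67 times as high in a region of 50 spots (9.06%, led by LYZ, TFF2 and TM4SF4). Acinar genes were 39.3 times as high in a region of 5 spots. Of 120 pairs 17 lay at or above the 99th percentile, beside 1.2 for 1% of the pairs, 1 of them with a ratio below 1.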

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

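Of 1711 values under alternatives, 1400 stayed on the same side with the same direction (for a count, within 1.5 times), 266 lost their call, 37 moved and 8 changed sign. The 1400 include values that had little room to change. No pair of lists passed in any setting, so a pair stayed the same unless its sign changed. A class share stayed the same within the SD over its libraries, 17.2 percentage points for ductal or cancer-like cells of B. For 103 genes followed through 1404 values, the direction was the same in 1403 and 1137 stayed past the threshold. These genes were followed because they passed in the main fit, and the alternatives reuse most of the same spots and cells. A shared direction was therefore likely beforehand, and these tallies are a weak measure of stability. The fits with and without F on the genes of its table, the ranking of cells within clusters and the levels without each ST section were chosen after seeing the data; the other alternatives were set before. For each changed value below, the cause was not tested unless the construction is named.

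The tumour block decided the calls. Without the block edgeR called 0 genes in the ST stress split (42 at an unadjusted p of 0.05), 0 in the cancer epithelium split (258) and 0 in the inDrop stress split (81), and 78 of 78 gene values lost their call, since the differences between tumours then enter the error.

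The ST stress split called 2 genes. It gave 4 with 4 parts, 0 with the score as a share of counts (637 at an unadjusted p of 0.05), 1 with first sections only, 1 with DESeq2 and 41 without the filter on low counts. Leaving out each tumour gave 1 to 31 (1 without A, 4 without E, 31 without G). On the genes of F's table it gave 0 with F (147 unadjusted) and 0 without F (154), where fewer genes were tested.

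The cancer epithelium split called 528 genes. It gave 257 with the score residual on the fibroblast score (243 shared), 223 with first sections only, 293 with DESeq2, and 241 to 607 with each tumour left out (241 without D, 244 without E). On the genes of F's table it gave 261 with F and 174 without, where fewer genes were tested, and 520, 595, 573, 625, 551 and 745 under the remaining alternatives. With the fibroblast score taken out, LUM, FBLN1, DCN, SPARC and LMOD1 were among the genes that lost their call.

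The inDrop stress split called 148 genes. It gave 226 with 4 parts, 78 with DESeq2 (fewer genes tested), 348 without the filter on low counts and 126 to 353 with each tumour left out (353 without B). With cells ranked within clusters it gave 167 (94 shared, 5 of the 148 with the other sign), and LY6D changed sign, from -1.44 to 0.49 (adjusted p = 0.49). In this alternative clusters add no difference between the parts, and KRT6A, KRT6B, KRT16 and CST6 were among the genes that lost their call.

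Among pairs of lists, 10 of 12 kept their sign. Stress response with inflammatory fibroblast genes (-0.0036) became 0.00985 with Pearson's r and 0.0483 as a partial correlation, and ran from -0.0631 to 0.0201 with each tumour left out (0.0155 without A, 0.017 without D, 0.0201 without E, 0.0139 without F). Stress response with macrophage and monocyte genes (-0.0175) became 0.00671 as a partial correlation. The smallest adjusted p in any setting was 0.094.

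Of class shares in the cells, the ductal or cancer-like share of A moved from 78.3% to 67.4% with at least 500 counts and to 75.3% at a resolution of 0.5, and that of C from 87.6% to 73.5% at that resolution. In A with at least 500 counts, T and NK-like cells moved to 1.5%, macrophage and monocyte-like to 5.93%, red blood cell-like to 1.39% and unnamed to 18.6%. At a resolution of 0.5, macrophage and monocyte-like cells of A moved to 5.65%, and unnamed to 10.7% in A and 23.0% in C. With at least 500 counts macrophage and monocyte-like cells of B moved to 2.23% and unnamed cells of C to 11.1%. In B at that minimum the ductal or cancer-like share went from 66.3% to 81.3% and the unnamed share from 23.4% to 8.20%, which is within the SD of its libraries, and T and NK-like cells appeared at 1.77%. In C macrophage and monocyte-like cells appeared at 2.49%. Other classes that appeared held 0.299% to 0.785% of a tumour. At that minimum no cluster was named endothelial-like in A (0.536% before), acinar-like in B (0.242%) or fibroblast-like in C (3.13%). Their cells can lie in unnamed clusters. At a resolution of 0.5 no cluster of B was named macrophage and monocyte-like (2.94% before), and a fibroblast-like class appeared there at 0.363%.

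Region and population pairs at the 99th percentile in B moved from 14.2% to 25% at a resolution of 0.5, where its regions went from 10 to 4 and none was led by C1QB, MMP11 or LYZ. In A the same share went from 20.7% to 21%, while its regions went from 7 to 5 and none was then led by PPY. Of the 24 named clone genes, 16 had at least 100 counts and kept their place, and the others could not be tested. The count of lists that differ at least 5-fold between tumours stayed within the limits above (14 to 16 without each section of A and B), but the highest or lowest tumour changed in 16 of 31 lists. In simulated ST splits, genes changed by 1 on the log2 scale, drawn among those with a mean of at least 32 CPM, were recovered in 60% (stress) and 58% (cancer epithelium) of cases.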

Other observations

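Single islet and exocrine genes stood out inside the tissue of A and B. In A, PPY led a region of 45 spots with CPA5, PRSS2, CEL and GP2, at 5.94 times the other spots, apart from the region of 43 spots led by CPB1 at 15.4 times. At a resolution of 0.5 A had 5 regions and none was led by PPY. In B, CRP led a region of 13 spots at 13.5 times, with DUOX2 beside it, and PNLIP a region of 5 spots at 295 times. At a resolution of 0.5 CRP led a region of 50 spots, and DUOX2 was not among its 5 leading genes. CRP is an acute-phase gene, and DUOX2 is the oxidase gene that rose with cancer epithelium over 5 tumours by 2.24 ± 0.27 (SE) on the log2 scale. Smooth muscle genes led another region of B, with ACTG2 at 13.4 times and DES at 12.9 times.

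The tests in this paragraph and the next had their predictions written before their results were seen, and leaving out each tumour was added after. The stress-response genes may vary together in the tissue itself and not only after dissociation. Over ST spots, where no cell was dissociated, their mean pairwise rho was 0.174 in 5 tumours, above the middle 95% of 200 random lists (0.108 to 0.16), but this rests on B (0.288 there): without B it was 0.145, inside its range (0.0964 to 0.147). With spots thinned to 500 counts it was 0.00773 (random lists -0.0023 to 0.00292) and stayed above without each tumour in turn, so spot depth is not the whole cause. Dissociation cannot cause a rho over spots of tissue that was not dissociated. How these genes vary together in the dissociated cells was not measured, so the part of dissociation there stays open. The value over thinned spots is small, and no biological explanation was tested.

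Stress response went with cancer epithelium in 6 of 6 tumours, F included, by Spearman's rho but in 4 of 6 by Pearson's r. Inside the epithelial cells the cancer epithelium list had a median of -0.18 (adjusted p = 0.460 in camera with an estimated correlation). The amount of epithelial RNA in a spot was weighed as a cause. Given the ductal score, the mean partial rho over 5 tumours was 0.0754 (500 random lists -0.0542 to 0.0541), but without A it was 0.0369, inside its range (-0.0702 to 0.0476), so epithelial content could be the cause and the test leaves it open. MHC class II genes went with T and NK genes in 5 of 5 tumours. Given the macrophage and monocyte, dendritic and B cell scores the mean partial rho was 0.127 (random lists -0.0338 to 0.0651). It stayed above them without each tumour in turn (0.119 to 0.134). Over these tumours T and NK genes stood at 91.9 to 449 CPM, so the score that makes this pair rests on few counts. Dendritic genes stood at 88.2 to 171 CPM and B cell genes at 13.6 to 77.0, so their scores do too. Taking out such scores can leave part of the cell content in place, so the test cannot exclude antigen-presenting cells. Epithelial cells that carry MHC class II genes, or cells the lists miss, could add to the rho, which was not tested.

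Exchanging the high and low sums within tumours asked how many genes other labellings of the same sums call. Each sum still comes from spots or cells ranked by expression. An exchange in some tumours sets their differences against those of the others, which can raise the error and lower the count. Low counts in the other exchanges are therefore not what a chance split of spots or cells gives. With 5 tumours there are 16 exchanges, too few to exclude chance: in the stress split 5 of 16 gave at least the real 2 genes, with up to 24 in the others. In the cancer epithelium split 1 of 16, the real one, gave 528 genes, and the highest other gave 71. In the cells 1 of 4, the real one, gave 148, and the highest other gave 1, again with too few exchanges. With 6 tumours on the genes of F's table, 1 of 32 gave the real 261 genes of the cancer epithelium split (highest other 71). For the stress split with F, edgeR called 0 genes (147 at an unadjusted p of 0.05, where DESeq2 was not run), so the exchanges say nothing there: any of them gives at least 0, and 32 of 32 did (highest other 14).

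Random lists used in place of the scored list gave a second comparison. For cancer epithelium, 0 of 20 random lists called as many as 528 genes in edgeR (median 43, highest 208). The random lists held only genes outside the fixed lists, so they cannot show what other lists of marker genes would call. For stress in the cells, 4 of 20 called as many as 148 (median 27, highest 286), so the count of genes there may partly reflect variation that many lists pick up, though 148 fell to 78 with DESeq2 and rose to 353 without tumour B. For stress in the tissue, 16 of 20 called as many as 2 (median 25.5).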
